A study of Mus musculus with 16 samples.

How the data were processed

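Bulk RNA sequencing of the hypothalamus of diet-induced obese C57BL/6J mice was analysed in 16 libraries, 4 in each of 4 groups. Per the labels' protocols, mice received daily DMSO injections for 1 week and were then divided at random into groups treated for 4 days. Veh mice received DMSO with free access to food, and CS mice received celastrol at 100 µg per kg per day with free access to food. PF mice received DMSO and a ration of 0.5 g of high-fat diet per day, given as 0.34 g in the dark and 0.16 g in the light, against an average of 0.8 g eaten by celastrol-treated mice. PF+CS mice received celastrol and the same ration. Tissue was taken 6 h after a last injection at about 8 am. RNA was extracted with a column kit and made into libraries with a SMARTer mRNA kit, per the labels' protocols. The labels state neither cages, litters, collection days nor the strand of the libraries, so mice that shared any of these were treated as independent.

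The authors deposited whole-number counts per gene and a second table of FPKM values for the same 16 libraries, together with 5 comparison tables. The second table is named as counts, but its values are fractions that fall with gene length, and it was read as FPKM. The deposited comparison tables hold a baseMean, a mean of normalised counts (a unit other than the rest), a log2 fold change with its standard error in log2 units, and a p-value with an adjusted p-value. Their names and columns point to DESeq2, run by the authors. The largest absolute log2 change in a table was 0.45 to 1.13, so sizes there cannot be set beside those of edgeR. Per the submitters' processing notes, the genome build was GRCm38. The aligner, the counter and the settings are not given in the sources used here. Gene positions, exons, transcript lengths and GC content came from an annotation of the same build (GENCODE M21). The blood glucose readings named in the labels were not used here.

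The count table lists 24047 genes. Of these, 27 carry names that a spreadsheet had turned into dates; they hold 0.22 to 0.24% of the counts of a library, and 23 of them were tested but never named. No column came from another series (0 columns). Library totals were 6008564 counts (PF 1) to 12880459 counts (Veh 3), with 16998 to 17961 genes having a count. The common biological coefficient of variation was 0.055. These depths were checked on simulated data, drawn for each gene by itself with the spread estimated for that gene. Differences that many genes of a library share were not simulated, so real recovery may be lower and false calls more. For PF minus Veh, 73 of 100 genes changed 1.5-fold and 88 of 100 changed 2-fold were called, with 8 false calls. For the interaction the same held for 122 of 200 and 160 of 200 with 13 false calls, and in CS minus Veh, left unchanged, there were 0 false calls.

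The choice of groups, comparisons, tests, gene lists and of the rule for named genes was made before the data were examined. Counts of all 16 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood method, with TMM scaling and filterByExpr at a minimum count of 10, which left 14775 genes. The 7 contrasts were the 6 differences between groups and the interaction, the celastrol effect under the ration minus that with free food. Genes were called at a Benjamini-Hochberg (BH) adjusted p of at most 0.05 within each contrast. Log2 changes carry their standard error (SE), and levels in CPM, counts scaled to library size, are means ± SD of 4 libraries. DESeq2 1.42.0 and voom in limma 3.58.1 were the other tools.

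A set of 38 gene lists was fixed from background knowledge. Of these, 36 had at least 3 measured members and were tested by camera on voom values with a preset correlation of 0.01, BH-adjusted over the lists. Beside it stand camera with the correlation estimated from the data, which takes into account that members of a list vary together, and fry. Lists defined by a name pattern had been stored with an altered separator and at first had no members, which left fewer lists to test; the patterns were then read from the file written with them. Member counts are given from the adjustment over all genes and from the adjustment over the list alone. The leptin signalling list holds inhibitors of the pathway, such as Socs3 and Ptpn1, beside its activators. The direction of that list is therefore not the direction of leptin signalling.

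Per 2-group contrast, the named genes were the 12 higher and 12 lower with the largest change among those called, with a mean log2 CPM of at least 1 and no overlap between the 4 and 4 libraries, leaving out provisional gene models. In the interaction up to 6 each way were to be named. Feeding genes called in a contrast were named there; Hdac6, Lepr, Socs3, Ptpn1, Il1r1, Agrp, Npy, Pomc and Cartpt were followed throughout, and up to 4 members with the smallest adjusted p were named from a list. Some genes that this rule names are not reported here.

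Alternatives chosen before the data were examined were other tools and scalings, filters and thresholds, the 2 groups alone, leaving out 1 library at a time and a block on replicate numbers. A second edgeR fit intended for the other table was replaced by a limma test of log2 FPKM with 1 added, because the second table does not hold counts. After the data were examined, these were added: a covariate of meningeal fibroblast markers, leaving out the 5 libraries low in them, an offset for GC content and length with and without the block, and the correlation of PF minus Veh with PF+CS minus CS. In the check that libraries match across the deposited tables, the measure was changed after its first result was seen: uncentred values did not match every library to its own name, and values centred per gene did. Genes with exons shared with another gene were looked up, because the strand is unknown and such counts may hold reads of the neighbour.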

Results

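The series asks which appetite-raising and appetite-lowering genes of the hypothalamus respond to celastrol, a plant triterpenoid that lowers food intake in obese mice, when celastrol-treated mice are set beside pair-fed and satiated ones. The hypothalamus holds the neurons through which leptin restrains feeding, and HDAC6, a cytoplasmic deacetylase, is named in the series title as a target whose inhibition restores leptin signalling. Hdac6 (X:7930120-7947889, GRCm38, protein-coding) was measured at 57.5 ± 5.18 CPM in Veh and Lepr, the leptin receptor (4:101717404-101815352, GRCm38, protein-coding), at 19.4 ± 2.19 CPM (SD, n = 4). By edgeR on all 16 libraries neither was called in any contrast, where Hdac6 differed by log2 −0.06 to 0.11 and Lepr by 0.04 to 0.41. Lepr did pass in PF+CS minus Veh in the authors' deposited table and in 3 other fits, given below.

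The names of the deposited comparison tables conflict with the names of the count columns. In the authors' deposited tables, the baseMean of each of 5 comparisons is an exact combination of 8 count columns (largest relative error 5.3e-15). The table named for Veh and CS was computed from the PF and Veh columns, that named for PF and Veh from the CS and Veh columns, and that named for PF and PF+CS from the CS and PF+CS columns. Thus 3 of 5 names do not match, and all 5 match once PF and CS are exchanged. The sample titles carry the same names as the count columns, and they are kept here as "labelled PF" and "labelled CS". If the tables are right instead, CS minus Veh and PF minus Veh below trade places, PF+CS minus PF and PF+CS minus CS trade places, and CS minus PF changes sign. PF+CS minus Veh and the interaction stay as they are.

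Markers of meningeal fibroblasts, cells of the membranes around the brain, were low in 5 libraries from all 4 groups (mean log2 CPM 2.25 to 2.53 in Veh 3, PF 1, PF 2, CS 2 and PF+CS 4, against 3.70 to 4.37 in the others). Rn45s, the ribosomal RNA precursor, held 4.30 ± 0.926% of counts in Veh, 3.17 ± 0.535% in PF, 2.73 ± 0.204% in CS and 3.21 ± 0.557% in PF+CS (SD, n = 4).

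**Figure D1:**
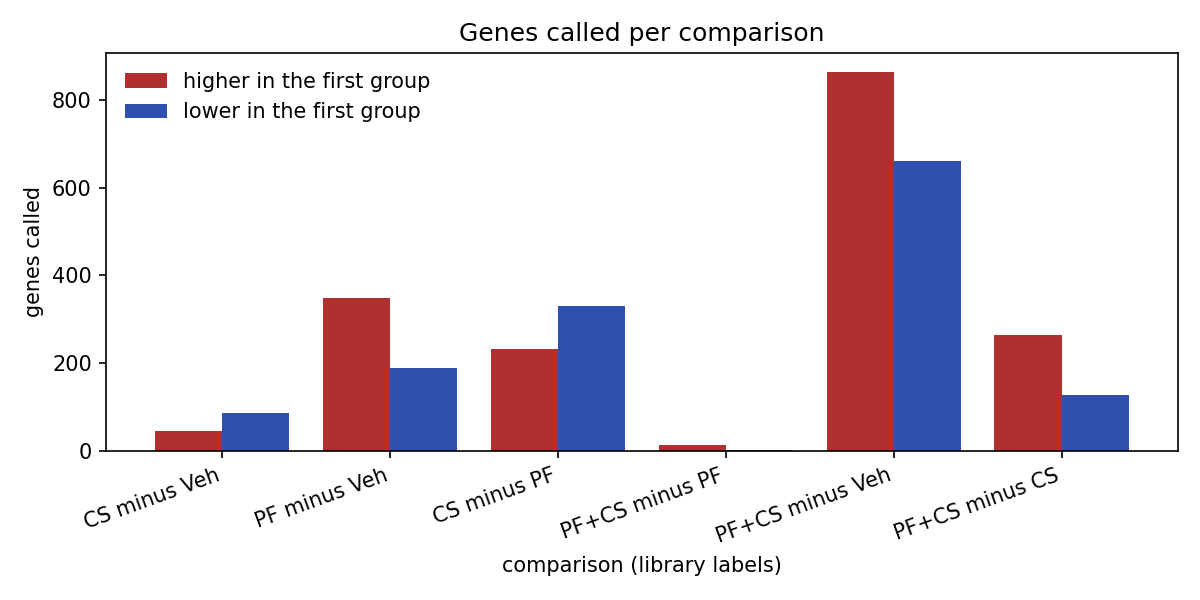
Number of genes called higher and lower (BH adjusted p ≤ 0.05, edgeR) in each of the 6 comparisons between groups, 4 libraries per group. Bars are counts of genes from 0.

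The comparison of the libraries labelled CS with Veh asks what celastrol does when food is freely available. Vgf, a secreted precursor of peptides that act on energy balance, had the smallest adjusted p and fell by 0.44 (SE 0.06, BH adjusted p = 0.00079, edgeR; 154 ± 2.78 CPM in CS and 208.5 ± 7.79 CPM in Veh, n = 4). Pomc, the precursor of the appetite-lowering melanocortins (12:3954951-3960642, GRCm38, protein-coding), fell by 0.73 (SE 0.13, adjusted p = 0.0107; 31.4 ± 6.32 CPM in Veh and 18.8 ± 2.32 CPM in CS, n = 4), a call that ended without CS 4 (adjusted p = 0.0674) and in the test of FPKM (0.0655). Fabp7, a fatty acid-binding protein of glia and tanycytes, fell by 0.80 (SE 0.12, adjusted p = 0.00122). Avp, the antidiuretic hormone vasopressin, fell by 0.97 (SE 0.18, adjusted p = 0.0286). Gal, the orexigenic peptide galanin, fell by 0.48 (SE 0.11, adjusted p = 0.027). Avp lost its call without Veh 1, Veh 2, CS 1, CS 3 or CS 4 (adjusted p 0.0714 to 0.131). Gal lost it without Veh 1, Veh 2 or any CS library (adjusted p 0.0526 to 0.131).

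Heg1, an endothelial junction receptor, rose by 0.49 (SE 0.08, adjusted p = 0.00277), and Flt1, a receptor for vascular endothelial growth factor, by 0.51 (SE 0.09, adjusted p = 0.00977; without Veh 2 adjusted p = 0.0598 and without CS 4 0.0624). Srrm2, a splicing scaffold, rose by 0.23 (SE 0.04, adjusted p = 0.00277), as did Safb2, a nuclear matrix protein, by 0.27, Clasrp, a splicing regulator, by 0.26 and Cnot3, of the deadenylase complex, by 0.28. Adap2 (0.47), an Arf GTPase regulator, Col11a1 (0.35), a fibrillar collagen, and Ick (0.30), a kinase of cilia, also rose. Ankrd24 (0.28), of stereocilia, Prrt1 (0.24), an AMPA receptor partner, and Hivep3 (0.23), a zinc-finger factor, were the other genes named by size. Lower were Chia1 (−0.94), a chitinase, Scarna2 (−0.65), a small nuclear RNA, Atp5e (−0.61), of ATP synthase, and Cited1 (−0.54), a coactivator. Mcat (−0.54), of mitochondrial fatty acid synthesis, Adra2c (−0.50), an adrenoceptor, Romo1 (−0.47), of the inner mitochondrial membrane, and Ngb (−0.47), neuroglobin, were lower as well.

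Of the ribosomal protein list (adjusted p = 2.1e-17, camera, adjusted p = 0.11 with an estimated correlation), 8 of 77 fell and 0 rose, and 40 fell adjusted over the list alone. Rplp1, of the ribosomal stalk, fell by 0.27 and Rpl37, Rps9 and Rps27a by 0.31, 0.23 and 0.30. Of nuclear oxidative phosphorylation genes (adjusted p = 4.95e-14, adjusted p = 0.0908 with an estimated correlation), 7 of 76 fell and 0 rose, 25 adjusted over the list alone, with Atp5g3 (−0.29), Uqcrfs1 (−0.26) and Cox5a (−0.26) at the head. Genes called lower had a median transcript length of 1933 bases and those called higher 7077, against 3446.5 for all tested. With an offset for GC content and length 3 ribosomal and 4 oxidative phosphorylation genes fell, and the median changes went from −0.127 to −0.054 and from −0.099 to −0.062. Lists called lower for neuroendocrine axes (1 of 16 fell, 3 adjusted over the list alone), cholesterol synthesis (0 of 19 and 0), astrocytes (0 of 13 and 4) and tanycytes (0 of 11 and 0) had adjusted p = 0.13, 0.584, 0.179 and 0.46 with an estimated correlation. Lists called higher for endothelium (1 of 10 rose, 1 adjusted over the list alone), oligodendrocytes (0 of 10 and 0) and thalamus (0 of 8, with 2 higher and 1 lower adjusted over the list alone) had adjusted p = 0.282, 0.584 and 0.564 with an estimated correlation. List calls also ended without 1 library, with the adjusted p after each: astrocytes (Veh 3 0.11), endothelium (Veh 3 0.186, CS 3 0.0554), oligodendrocytes (Veh 1 0.207, Veh 4 0.0868, CS 1 0.157) and tanycytes (Veh 1 0.0699, CS 1 0.0876). Others were thalamus (Veh 3 0.0638, Veh 4 0.0797, CS 1 0.0965).

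In all, 132 of 14775 genes were called (45 higher and 87 lower, with 6 changed at least 1.5-fold, all lower), and 125 of them had no overlap between groups. Among all tested genes, called or not, 8.94% had none, against 2.86% by chance. Of the genes followed throughout, Hdac6 (0.02), Lepr (0.14), Socs3 (−0.15), Ptpn1 (−0.11), Il1r1 (0.31), Agrp (0.21), Npy (0.28) and Cartpt (−0.31) did not pass by edgeR. Cartpt passed by DESeq2 (−0.30, adjusted p = 0.0396), with the 2 groups alone (−0.31, 0.047), without the 5 libraries low in meningeal markers (−0.40, 0.00735) and in the authors' deposited table from the CS and Veh columns (−0.229, 0.0119). The count was 51 without Veh 1, 14 without Veh 2, 242 without Veh 3, 201 without Veh 4, 46 without CS 1, 83 without CS 2, 42 without CS 3 and 10 without CS 4. Of the 24 genes named by size only Fabp7, Heg1 and Srrm2 kept their call in every such fit. Vgf and Rplp1 did so too. DESeq2 called 282, voom 228, and the test of FPKM 11, in which 3 of the 24 passed.

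The libraries labelled PF were compared with Veh to show what the food ration does without celastrol. Lcn2, an iron-carrier protein of the acute phase (2:32384633-32388252, GRCm38, protein-coding), rose by 4.85 (SE 0.97, adjusted p = 0.0192, edgeR; 0.620 ± 0.711 CPM in Veh and 18.0 ± 12.8 CPM in PF, n = 4). It lost its call without Veh 1 (adjusted p = 0.0628), Veh 2 (0.0806) or PF 4 (0.0825), in voom (0.104) and with the 2 groups alone (0.054). Tmem252, a transmembrane protein of little-known function, rose by 4.59 (SE 0.68, adjusted p = 0.00472), and Cebpd, a transcription factor of the acute-phase response, by 2.39 (SE 0.30, adjusted p = 0.000835). Ch25h, which makes 25-hydroxycholesterol, had the smallest adjusted p among list members, with 3.97 (adjusted p = 8.62e-06; 0.165 ± 0.133 CPM in Veh and 2.90 ± 0.624 CPM in PF, n = 4). Il1r1, the interleukin-1 receptor (1:40225080-40317257, GRCm38, protein-coding), rose by 1.48 (SE 0.24, adjusted p = 0.00671; 7.40 ± 1.61 CPM in Veh and 21.1 ± 5.39 CPM in PF, n = 4). Pomc fell by 0.75 (SE 0.13, adjusted p = 0.00451). Ghsr, the ghrelin receptor, rose by 0.68 (SE 0.16, adjusted p = 0.0222). Its call ended without Veh 2 (adjusted p = 0.101), Veh 4 (0.0646) or PF 4 (0.127). Agrp, the orexigenic melanocortin antagonist whose locus (8:105566698-105637393, GRCm38) overlaps Gm5914 and Ctcf, was at 0.65 (adjusted p = 0.0704) and passed without PF 3 (0.71, adjusted p = 0.0497) and with an offset for GC content and length (0.72, adjusted p = 0.0468).

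Other genes that rose were Cdkn1a (2.50), a cell-cycle inhibitor, Ptgs2 (2.10), the inducible prostaglandin synthase, Map3k6 (1.85), a stress kinase, and Runx1 (1.80), a transcription factor of blood and microglia. Zbtb16 (1.73) and Sgk1 (1.57), glucocorticoid-induced, Arl4d (1.70), a small GTPase, Apold1 (1.59), an early-response gene of endothelium, and Pla2g3 (1.48), a secreted phospholipase, rose as well. Lower were Gbp4 (−2.09), an interferon-induced GTPase with close relatives at its locus, and Clec14a (−1.14), an endothelial lectin. Bfsp1 (−1.05), a filament protein, Col14a1 (−1.03), a fibril-associated collagen, Serpinb1a (−0.95), a protease inhibitor, and Nes (−0.94), of progenitors and endothelium, were also lower. P2ry13 (−0.92), a purine receptor, and Aif1 (−0.84) mark microglia. AI854517 (−0.89) is a transcript of unknown function, Nipal4 (−0.86) a magnesium transporter, Oacyl (−0.84) an acyltransferase, and Dbp (−0.81, SE 0.13, adjusted p = 0.00451) an output gene of the circadian clock. The selectins Sele and Selp, which bind leucocytes to activated endothelium, were called from few counts. Sele had 60 counts in PF and 1 in Veh (ratio 72.4, 95% counting interval 12.5 to 2910), and Selp had 41 and 1 (ratio 49.4, 8.39 to 2000). Here and below, such intervals come from counts summed over the libraries of a group and leave out the spread between mice.

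The glucocorticoid-responsive list was higher in PF (adjusted p = 3.99e-18, camera, adjusted p = 0.212 with an estimated correlation). Of 20, 8 rose and 0 fell, 15 adjusted over the list alone, among them Plekhf1 (1.13, adjusted p = 0.00069), an endosomal protein, Arrdc2 (1.45), an arrestin-like protein, and Pdk4 (1.35). Heat shock genes (adjusted p = 2.8e-14, adjusted p = 0.212 with an estimated correlation) rose in 9 of 20 and fell in 0, 17 adjusted over the list alone, with the chaperones Hsp90aa1 (0.24), Hsph1 (0.40), Hspe1 (0.28) and Ahsa1 (0.25). NF-kB genes rose in 6 of 14 (6 adjusted over the list alone, Nfkbia 1.30), with adjusted p = 0.157 with an estimated correlation. Cytokine STAT3 genes rose in 5 of 19 (9 adjusted over the list alone, Osmr 1.35), with adjusted p = 0.212 with an estimated correlation. The unfolded protein response rose in 2 of 23 (4 adjusted over the list alone, Hsp90b1, the endoplasmic chaperone, 0.23, adjusted p = 0.212 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 19 (10 adjusted over the list alone, adjusted p = 0.212 with an estimated correlation). Insig1, partner of the sterol sensor, fell by 0.40 (adjusted p = 6.59e-05) and Lss by 0.31. Clock genes were lower as a set, with 4 lower and 2 higher of 17 (7 and 4 adjusted over the list alone, adjusted p = 0.239 with an estimated correlation). Among them were Bhlhe40 (−0.36), Nr1d1 (−0.39) and Npas2 (0.42).

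The orexigenic list was higher, with Ghsr and the cannabinoid receptor Cnr1 (0.15) as the 2 of 11 that rose (4 adjusted over the list alone, adjusted p = 0.212 with an estimated correlation). Cnr1 did not pass without Veh 1, Veh 2, Veh 4, PF 2, PF 3 or PF 4 (adjusted p 0.0577 to 0.136). Genes of the leptin signalling list rose in 3 of 20 (4 adjusted over the list alone) with Il1r1, Pik3r1 (0.17) and the phosphatase Ptpn2 (0.30). Insulin and FoxO targets rose in 2 of 12 and fell in 1 (6 and 1 adjusted over the list alone) with Sesn1 (0.34), Bcl6 (0.69) and Fbxo32 (−0.38). For each, adjusted p = 0.239 with an estimated correlation. Striatum markers rose in 1 of 8 (3 adjusted over the list alone, Gpr6, an orphan receptor of striatal neurons, 1.40, adjusted p = 0.212 with an estimated correlation). Lists called lower were oligodendrocytes (1 of 10 fell; 4 lower and 1 higher adjusted over the list alone, Cnp −0.34), oxidative phosphorylation (3 of 76; 3), ribosomal proteins (1 of 77; 0), interferon response (0 of 15; 0) and microglia (1 of 13; 2), with adjusted p = 0.27, 0.27, 0.418, 0.408 and 0.507 with an estimated correlation. The list calls that ended without 1 library, with the adjusted p, were clock genes (Veh 1 0.0511, PF 1 0.0692, PF 3 0.06), microglia (Veh 3 0.2, Veh 4 0.0902, PF 1 0.0706, PF 4 0.204), orexigenic genes (Veh 1 0.0877, Veh 3 0.108, PF 1 0.075, PF 4 0.108) and striatum (Veh 1 0.0514).

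In all, 537 genes were called (348 higher and 189 lower, with 122 changed at least 1.5-fold), 426 of them without overlap. Among all tested genes, called or not, 8.26% had none, against 2.86% by chance. Hdac6 (−0.06), Lepr (0.04), Socs3 (0.90), Ptpn1 (0.07), Npy (0.18) and Cartpt (−0.15) did not pass by edgeR. The count was 218 without Veh 1, 111 without Veh 2, 810 without PF 3 and 120 without PF 4. Tmem252, Cebpd, Gbp4, Bfsp1, P2ry13, AI854517 and Dbp were the 7 of 24 named by size that kept their call without any 1 library. So did Pomc, Il1r1, Ch25h, Nfkbia, Osmr, Plekhf1, Arrdc2, Hsp90aa1, Hsp90b1, Insig1, Bhlhe40, Nr1d1, Sele and Selp among list members. The 2 groups alone gave 284 calls and the test of FPKM 87 (35 higher, 52 lower), in which 11 of the 24 passed.

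**Figure D2:**
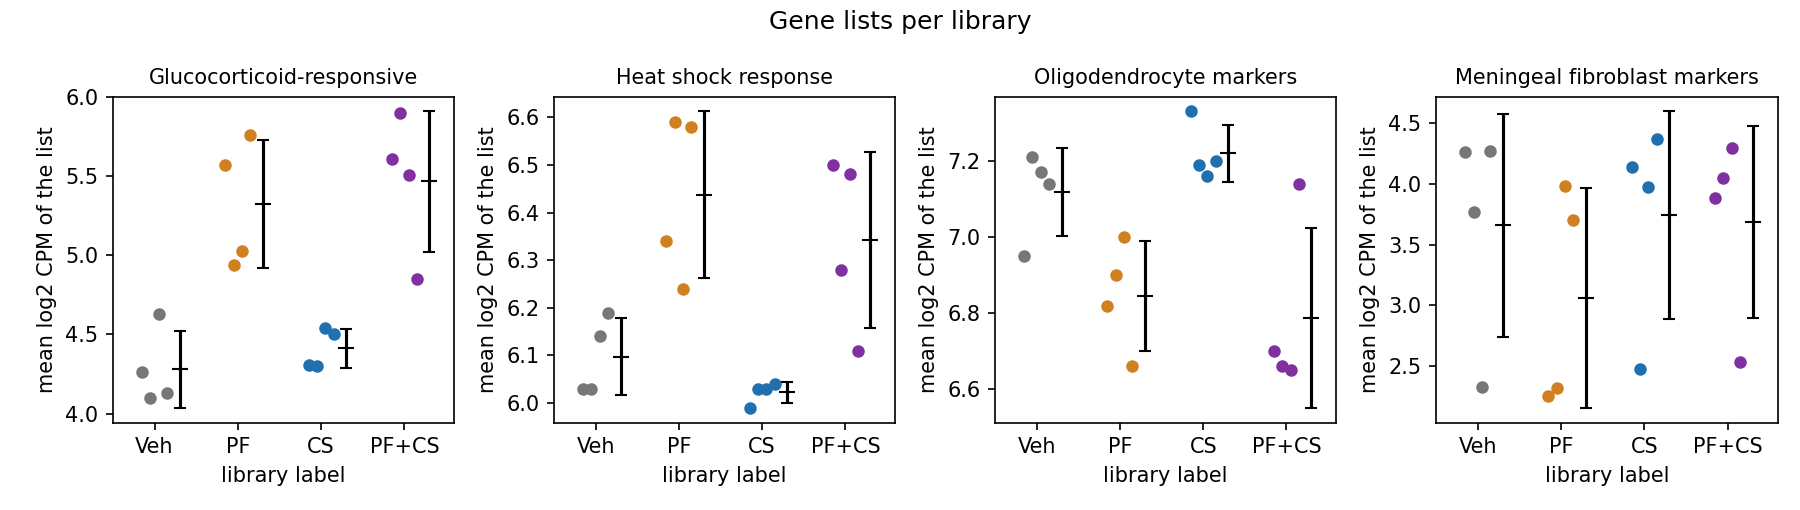
Mean log2 CPM of the glucocorticoid-responsive, heat shock, oligodendrocyte and meningeal lists in each library, by group. Points are libraries; bars are mean ± SD, n = 4.

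The difference between the libraries labelled CS and those labelled PF sets celastrol with free food against the ration without celastrol, and its sign depends on which names are right. Food intake was not matched (a ration of 0.5 g per day in PF against an average of 0.8 g eaten by celastrol-treated mice), so a change here may come from celastrol or from intake. Hsp90aa1, the stress-inducible cytosolic chaperone, had the smallest adjusted p and fell by 0.33 (adjusted p = 0.000372, edgeR; 721 ± 7.72 CPM in CS and 908 ± 73.1 CPM in PF, n = 4). Cd14, a receptor for bacterial lipopolysaccharide, fell by 2.04 (adjusted p = 0.000572), Cebpd by 2.14 (adjusted p = 0.00112) and Tmem252 by 3.89 (adjusted p = 0.00645). Dbp rose by 0.94 (adjusted p = 0.00133; 65.6 ± 6.87 CPM in CS and 34.3 ± 4.87 CPM in PF, n = 4), and Gal fell by 0.50 (SE 0.11, adjusted p = 0.00892; 17.1 ± 0.770 CPM in CS and 24.4 ± 3.82 CPM in PF, n = 4). Of other feeding genes, Ghsr fell by 0.69 (adjusted p = 0.0234), Cnr1 by 0.18 (adjusted p = 0.0114), the melanocortin receptor Mc4r by 0.74 (adjusted p = 0.0264) and the calcitonin receptor Calcr by 0.30 (adjusted p = 0.0234). Il1r1 fell by 1.17 (adjusted p = 0.0187).

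Some of these calls rested on single libraries. Il1r1 lost its call without PF 1, PF 4, CS 1 or CS 3 (adjusted p 0.0561 to 0.0739), Ghsr without PF 1, PF 4 or any CS library (0.0513 to 0.112). Mc4r lost it without PF 2, PF 4, CS 1, CS 3 or CS 4 (0.0581 to 0.0995), and Calcr without PF 2, PF 4, CS 1 or CS 4 (0.0719 to 0.132). Cnr1 lost it without PF 4 (0.0511) or CS 3 (0.0614). Gal lost its call only in the test of FPKM (adjusted p = 0.0552) and without the 5 libraries low in meningeal markers (adjusted p = 0.053). Lcn2 (−4.44) lost it without PF 1, PF 4 or any CS library (0.0512 to 0.0818).

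Further genes lower in the libraries labelled CS were Cdkn1a (−2.83), Ptgs2 (−1.89), Hspa1b (−1.86), an inducible chaperone whose reads can hardly be told from those of Hspa1a, and Pla2g3 (−1.60). Pmaip1 (−1.56), a proapoptotic gene, Apold1 (−1.41), Pdk4 (−1.38), a fasting-induced kinase, and Gpr6 (−1.37) were lower too. Higher were the interferon-induced Gbp4 (1.81) and Sp100 (1.23), the endothelial genes Clec14a (1.33) and Sox18 (1.13), Ushbp1 (1.17), a binding partner of harmonin, and Tdrd9 (1.19), a germ-cell helicase. Enpp6 (1.03), of newly formed oligodendrocytes, Serpinb1a (0.99), Itpr3 (0.97), a calcium channel, Cxcl12 (0.94), a chemokine, and Haus5 (0.87), of the spindle, were higher as well.

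Heat shock genes were lower (adjusted p = 1.57e-18, camera, adjusted p = 0.0792 with an estimated correlation). Of 20, 13 fell and 0 rose, 18 adjusted over the list alone, with Hsp90ab1 (−0.22), the co-chaperone Fkbp4 (−0.32) and Hsph1 (−0.52). The unfolded protein response fell in 8 of 23 (10 adjusted over the list alone, Hsp90b1 −0.25, Pdia6 −0.28, Hyou1 −0.20, Pdia4 −0.31). Cytokine STAT3 genes fell in 5 of 19 (10 adjusted over the list alone, Ch25h −2.42, Osmr −1.18) and NF-kB genes in 5 of 14 (5). Each of the 3 lists had adjusted p = 0.0792 with an estimated correlation. In NF-kB genes Sele had 60 counts in PF and 3 in CS (ratio 23.4, 95% counting interval 7.64 to 117). Glucocorticoid-responsive genes fell in 5 of 20 (16 adjusted over the list alone, Arrdc2 −1.30, Plekhf1 −0.79, Ddit4, an mTOR inhibitor, −1.13), with adjusted p = 1.45e-14 and adjusted p = 0.141 with an estimated correlation. Oligodendrocyte genes rose in 2 of 10 (8 adjusted over the list alone, Ermn 0.38, and the myelin gene Mbp 0.23, adjusted p = 0.105 with an estimated correlation). Clock genes rose in 6 of 17 with 1 lower (10 and 4 adjusted over the list alone, Bhlhe41 0.25, Bhlhe40 0.29, Npas2 −0.53, adjusted p = 0.0792 with an estimated correlation).

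The orexigenic list (3 of 11 fell; 4 lower and 1 higher adjusted over the list alone) and the anorexigenic list (2 of 19 fell; 4) were both lower, with adjusted p = 0.141 and 0.139 with an estimated correlation. AgRP neuron-enriched genes fell in 2 of 10 (4 adjusted over the list alone, Ghsr, and Vgf −0.23, which did not pass without PF 1, PF 2, CS 1, CS 3 or CS 4, 0.074 to 0.102). Genes of the leptin signalling list fell in 2 of 20 (6). Each of these lists had adjusted p = 0.141 with an estimated correlation. Neuroendocrine genes fell in 1 of 16 (7 adjusted over the list alone, Crym, a thyroid hormone-binding protein, −0.78, adjusted p = 0.0792 with an estimated correlation). Lists called lower for ribosomal proteins (0 of 77 fell, 0 adjusted over the list alone), oxidative phosphorylation (0 of 76, 0) and insulin and FoxO targets (2 of 12 fell and 1 rose; 4 and 1) had adjusted p = 0.272 with an estimated correlation. Of those called higher, the interferon response (0 of 15 rose, 0 adjusted over the list alone) and endothelium (1 of 10; 3 higher and 2 lower) had adjusted p = 0.272 with an estimated correlation, and cholesterol synthesis (1 of 19; 1; Insig1 0.32), meninges (0 of 9; 0) and mural cells (1 of 9; 1; Pdgfrb 0.40) had 0.381, 0.5 and 0.298. Calls of lists lost without 1 library, with the adjusted p, were anorexigenic genes (PF 2 0.154, CS 3 0.0628), cholesterol synthesis (PF 2 0.139), endothelium (PF 1 0.125, PF 2 0.106, PF 3 0.0928, CS 3 0.164, CS 4 0.134) and meninges (PF 1 0.0837, PF 2 0.149, CS 4 0.111). Others were mural cells (PF 1 0.051, PF 2 0.126, CS 4 0.0998), oxidative phosphorylation (PF 1 0.051) and orexigenic genes (PF 1 0.0521, PF 4 0.111, CS 4 0.134).

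In all, 561 genes were called (231 higher and 330 lower, with 137 changed at least 1.5-fold), 473 of them without overlap. Among all tested genes, called or not, 10.7% had none, against 2.86% by chance. Hdac6 (0.08), Lepr (0.10), Socs3 (−1.05), Ptpn1 (−0.18), Agrp (−0.44), Npy (0.09), Pomc (0.02) and Cartpt (−0.16) did not pass by edgeR. In the authors' deposited table from the CS and PF columns Socs3 passed (−0.286, adjusted p = 0.0135). The count was 245 without PF 1, 214 without PF 4, 217 without CS 1, 283 without CS 3 and 190 without CS 4. Cd14, Cebpd, Clec14a, Dbp, Gbp4, Gpr6, Itpr3, Pla2g3, Pmaip1 and Tmem252 were the 10 of 24 named by size that kept their call in every such fit. Gal, Arrdc2, Plekhf1, Ch25h, Osmr, Hsp90aa1, Hsp90ab1, Hsp90b1, Hsph1, Fkbp4, Insig1, Bhlhe40, Bhlhe41, Npas2 and Sele did so too. The test of FPKM called 119 genes, 10 of the 24 among them.

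By the column names, PF+CS minus PF asks what celastrol adds when all mice receive the same ration. Few genes differed, 14 in all. Kmt2d, a histone methyltransferase, had the smallest adjusted p and rose by 0.25 (SE 0.04, adjusted p = 0.00426, edgeR; 447 ± 10.6 CPM in PF+CS and 374 ± 13.5 CPM in PF, n = 4). Heg1 rose by 0.43 (adjusted p = 0.0149) and Col11a1 by 0.42, both also called in CS minus Veh, and the basement-membrane collagen Col4a2 by 0.30. Vgf, the only gene lower, fell by 0.29 (adjusted p = 0.0475), which did not pass without PF 1, PF 2 or any PF+CS library (adjusted p 0.0881 to 0.233).

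The other genes named by size that rose were Coro6 (0.52), an actin-binding protein, Adamts10 (0.49), a matrix protease, and Akap8l (0.30), a nuclear anchoring protein. Lrrc16b (0.30), of actin capping, Arhgef2 (0.29), a guanine nucleotide exchange factor, Leng8 (0.26), of mRNA export, Celsr3 (0.23), an axon guidance cadherin, and Nav2 (0.22), a neuron navigator, rose as well. Coro6 lost its call without PF 1 (adjusted p = 0.0548) or PF 2 (0.121), Adamts10 (0.0612 to 0.127) and Heg1 (0.0758 to 0.166) without PF 1, PF 2, PF+CS 2 or PF+CS 3, and Nav2 without PF 2 (0.077).

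Endothelial genes were higher as a set, and this was the only list in any contrast called with an estimated correlation as well (adjusted p = 4.33e-08, camera, and adjusted p = 0.0336 with an estimated correlation). Of its members, 0 of 10 passed over all genes and 2 rose adjusted over the list alone. Mural cells (0 of 9 passed, 1 adjusted over the list alone), meninges (0 of 9, 0) and the interferon response (0 of 15, 0) were called higher, with adjusted p = 0.154, 0.632 and 0.69 with an estimated correlation. Ribosomal proteins (0 of 77, 0), oxidative phosphorylation (0 of 76, 3), anorexigenic genes (0 of 19, 1), neuroendocrine genes (0 of 16, 0), astrocytes (0 of 13, 0) and NRF2 targets (0 of 15, 1) were called lower, with adjusted p = 0.154, 0.0716, 0.0716, 0.154, 0.154 and 0.154 with an estimated correlation. Heat shock (0 of 20, 0), the unfolded protein response (0 of 23, 0), cholesterol synthesis (0 of 19, 0) and neurons (0 of 10, 2) were called lower too, with adjusted p = 0.575, 0.494, 0.632 and 0.575 with an estimated correlation. List calls lost by leaving out 1 library, with the adjusted p, were NRF2 targets (PF 1 0.0759, PF 3 0.0861, PF+CS 3 0.0563), anorexigenic genes (PF 2 0.0609), astrocytes (PF 1 0.0906, PF+CS 1 0.0544) and cholesterol synthesis (PF 1 0.0956, PF 3 0.393, PF 4 0.0551, PF+CS 1 0.0784, PF+CS 3 0.398). Others were heat shock (PF 4 0.131, PF+CS 4 0.0728), the interferon response (PF 1 0.136, PF 2 0.11, PF 4 0.196, PF+CS 4 0.986), meninges (PF 1 0.0841, PF 2 0.203, PF+CS 3 0.12) and neuroendocrine genes (PF 2 0.0796). Others were neurons (PF 2 0.312, PF+CS 1 0.147, PF+CS 3 0.0819) and the unfolded protein response (PF 4 0.301, PF+CS 4 0.221).

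Of the 14 genes called, 13 were higher and 1 lower, 0 changed 1.5-fold, and all 14 had no overlap. Among all tested genes, called or not, 4.16% had none, against 2.86% by chance, and 1160 had an unadjusted p under 0.05. Hdac6 (0.11), Lepr (0.37), Socs3 (0.06), Ptpn1 (0.12), Il1r1 (0.20), Agrp (0.02), Npy (0.16), Pomc (−0.08) and Cartpt (−0.15) did not pass by edgeR. The count was 3 without PF 1, 1 without PF 2, 24 without PF 4, 6 without PF+CS 2 and 7 without PF+CS 3. Of the 13 genes named by size, Vgf among them, only Kmt2d passed in every such fit. DESeq2 called 29, voom 5, the 2 groups alone 7, the test of FPKM 0, and the fit without the 5 libraries low in meningeal markers 0.

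PF+CS minus Veh asks what celastrol and the ration do together, and does not depend on which names are right. It held the most calls. Lcn2 rose by 5.35 (SE 0.93, adjusted p = 0.0041, edgeR; 26.0 ± 16 CPM in PF+CS and 0.620 ± 0.711 CPM in Veh, n = 4), Tmem252 by 4.59 (adjusted p = 0.00163) and Il1r1 by 1.67 (SE 0.24, adjusted p = 0.00102; 24.0 ± 5.34 CPM in PF+CS and 7.40 ± 1.61 CPM in Veh, n = 4). Pomc fell by 0.84 (SE 0.13, adjusted p = 0.000634; 17.5 ± 1.81 CPM in PF+CS and 31.4 ± 6.32 CPM in Veh, n = 4) and Vgf by 0.50 (SE 0.06, adjusted p = 1.39e-05). Agrp rose by 0.67 (adjusted p = 0.0328), Npy, its orexigenic partner in the same neurons, by 0.34 (adjusted p = 0.0456), and Ghsr by 0.68 (adjusted p = 0.00983). Gal fell by 0.43 (adjusted p = 0.0113) and Trh, the anorexigenic thyrotropin-releasing hormone, by 0.34 (adjusted p = 0.0424).

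Calls of Agrp, Npy, Gal and Trh depended on single libraries. Those of Pomc and Vgf did not, with an adjusted p of at most 0.0047 and 0.000245 by edgeR in every fit without 1 library. Agrp did not pass without Veh 1, Veh 2, Veh 3, PF+CS 1, PF+CS 2 or PF+CS 3 (adjusted p 0.0525 to 0.104; DESeq2 0.0805). Npy did not pass without any 1 Veh library, PF+CS 1 or PF+CS 3 (0.0513 to 0.217; DESeq2 0.0768; voom 0.0535). Gal did not pass without Veh 1 (0.0529) or PF+CS 3 (0.0593), and Trh passed without PF+CS 1 only (0.0581 to 0.121 in the 7 other fits). Without PF+CS 4, Socs3, a leptin-induced inhibitor of the leptin receptor (1.2, adjusted p = 0.0286), Ptpn1, a phosphatase that dampens leptin signalling (0.25, adjusted p = 0.029), and Cartpt, an anorexigenic peptide (−0.34, adjusted p = 0.0386), passed.

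Further genes that rose were Cdkn1a (2.64), Lrg1 (2.57), an acute-phase glycoprotein, Cebpd (2.32), Map3k6 (2.31) and Ptgs2 (2.16). Zbtb16 (1.99), Xdh (1.91), xanthine dehydrogenase, Runx1 (1.78), Arl4d (1.68) and Angptl4 (1.68), a fasting-induced lipase inhibitor, rose too. Lower were Snord22 (−1.28), a small nucleolar RNA inside Snhg1, Serpinb1a (−1.21), Fzd10 (−1.01), a Wnt receptor, Nkx6-2 (−0.88), a factor of oligodendrocytes, and Dbp (−0.86). Nes (−0.85), Bfsp1 (−0.83), Lrrc10b (−0.82), a leucine-rich repeat protein, Creb5 (−0.81), a transcription factor, Sox21 (−0.80), of glia, and Avp (−0.80) were lower as well.

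**Figure D3:**
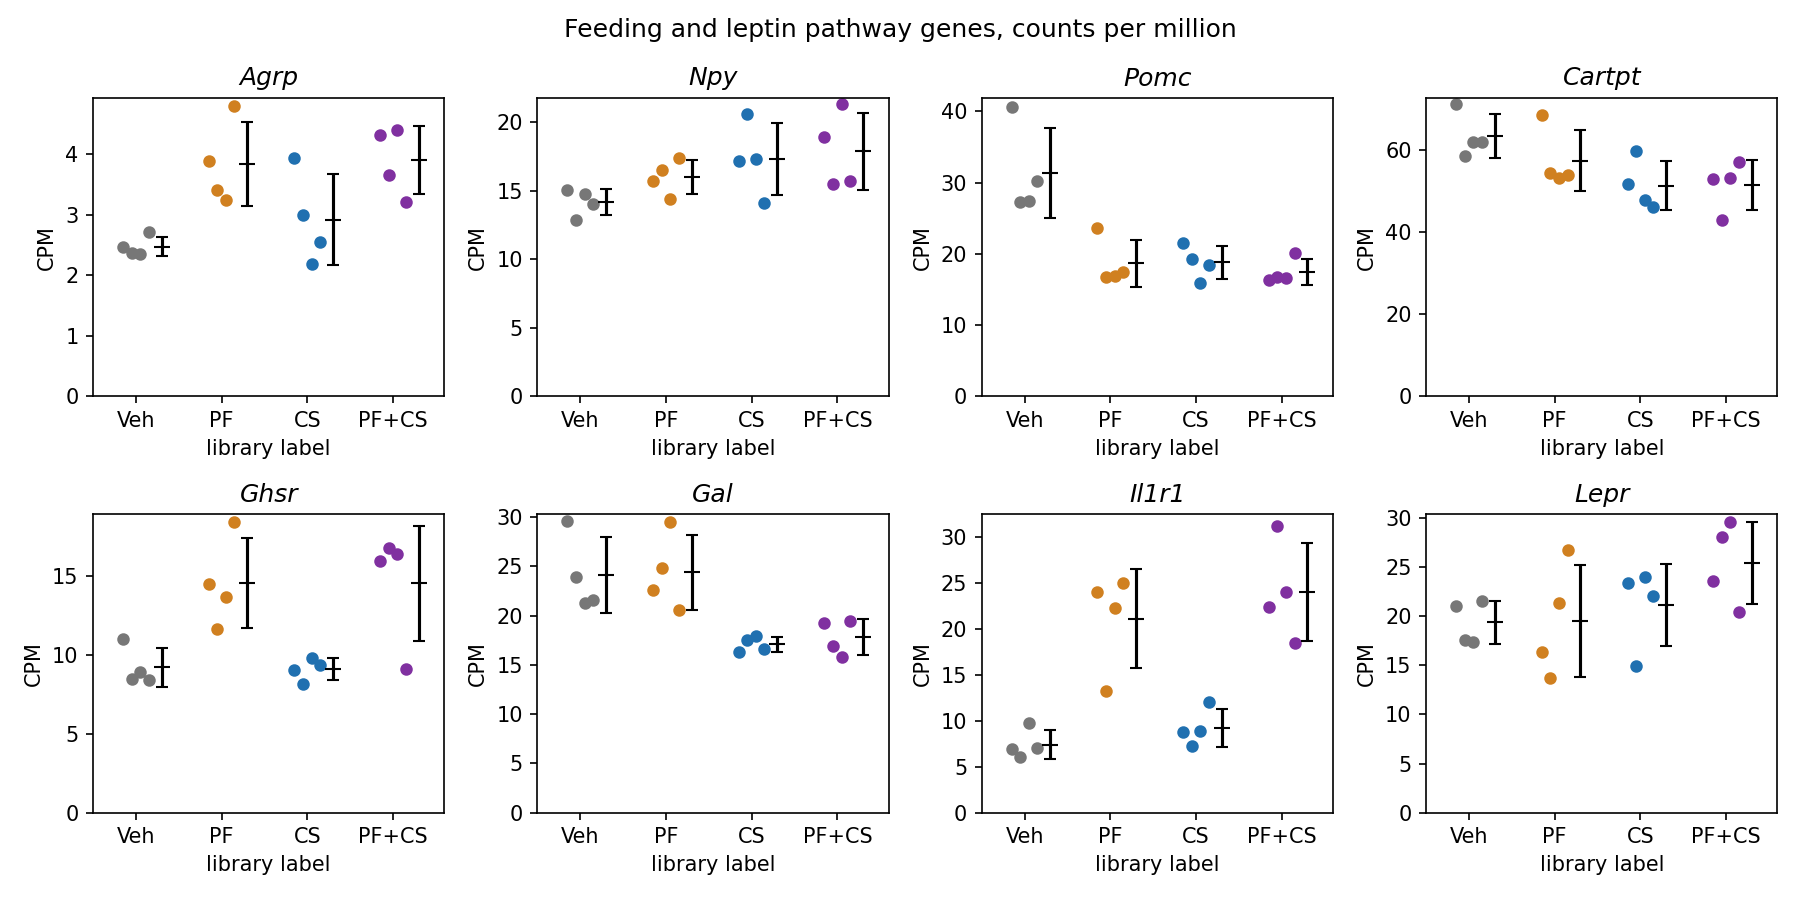
CPM of Agrp, Npy, Pomc, Cartpt, Ghsr, Gal, Il1r1 and Lepr in each library, by group. Points are libraries; bars are mean ± SD, n = 4.

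Glucocorticoid-responsive genes rose in 16 of 20 with 0 lower (18 adjusted over the list alone, adjusted p = 8.95e-18, camera, adjusted p = 0.147 with an estimated correlation): Plekhf1 by 1.13, Arrdc2 by 1.44 and Sgk1 by 1.63. The list stood at a mean log2 CPM of 4.28 ± 0.243 in Veh and 5.47 ± 0.444 in PF+CS (SD, n = 4), with PF+CS 4 at 4.85. Cytokine STAT3 genes rose in 8 of 19 and fell in 1 (9 and 1 adjusted over the list alone, Ch25h 3.94, Osmr 1.63, Il6ra 0.92), with adjusted p = 0.147 with an estimated correlation. NF-kB genes rose in 6 of 14 (8 adjusted over the list alone, Nfkbia 1.23), with adjusted p = 0.105 with an estimated correlation. Sele had 54 counts in PF+CS and 1 in Veh (ratio 57.4, 95% counting interval 9.87 to 2310), and Selp 69 and 1 (ratio 73.3, 12.7 to 2940). Endothelial genes rose in 4 of 10 (4 higher and 1 lower adjusted over the list alone, Flt1 0.72, Ly6c1 0.82, the glucose transporter Slc2a1 0.97, Pecam1 0.66, adjusted p = 0.147 with an estimated correlation). Reads of Ly6c1 may be shared with its close relatives.

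Ribosomal proteins fell in 21 of 77 with 0 higher (40 adjusted over the list alone, adjusted p = 7.04e-14, camera; Rplp1 −0.28, Rpl13a −0.17, Rps9 −0.22, Rpl37 −0.26). Oxidative phosphorylation fell in 24 of 76 with 0 higher (30, adjusted p = 2.12e-13, Cox4i1 −0.23, Cox5a −0.31, Atp5g3 −0.29, Atp5j2 −0.27). These lists had adjusted p = 0.137 and 0.105 with an estimated correlation. Genes called lower had a median transcript length of 2787.5 bases and those called higher 4729, against 3446.5 for all tested. With an offset for GC content and length 11 ribosomal and 18 oxidative phosphorylation genes fell, and the median changes went from −0.12 to −0.057 and from −0.125 to −0.063. Cholesterol synthesis fell in 8 of 19 (14 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation) with Insig1 (−0.38), Fdps (−0.45), Sqle (−0.25) and Fdft1 (−0.26). Heat shock genes rose in 4 of 20 (8 adjusted over the list alone, Hsph1 0.32, Hsp90aa1 0.15, adjusted p = 0.27 with an estimated correlation). Insulin and FoxO targets rose in 4 of 12 and fell in 1 (7 and 1 adjusted over the list alone, Sesn1 0.36, Txnip 1.25, Bcl6 0.70, Foxo1 0.30). Genes of the leptin signalling list rose in 4 of 20 (4 adjusted over the list alone, Il1r1, Pik3r1 0.15, Ptpn2 0.31, Foxo1). For each, adjusted p = 0.207 with an estimated correlation. Clock genes were lower as a set (5 fell and 4 rose of 17; 8 and 5 adjusted over the list alone, Bhlhe40 −0.40, Bhlhe41 −0.25, Nr1d1 −0.34, adjusted p = 0.232 with an estimated correlation).

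Oligodendrocyte genes were lower as a set (1 of 10 fell and 1 rose; 6 lower and 1 higher adjusted over the list alone, Cnp −0.40, Mobp 0.31, adjusted p = 0.247 with an estimated correlation), and PF+CS 4 was near Veh (mean log2 CPM of the list 7.14, against 6.65 to 6.70 in the other PF+CS libraries and 7.12 ± 0.115 in Veh, SD, n = 4). Astrocyte markers fell in 3 of 13 (3 adjusted over the list alone, the GABA transporter Slc6a11 −0.21). NRF2 targets fell in 3 of 15 (3 lower and 1 higher; Sqstm1 −0.19, Prdx1 −0.22). For each, adjusted p = 0.207 with an estimated correlation. Striatum markers rose in 3 of 8 (3 adjusted over the list alone, Rgs9 0.21, Gpr6 1.03, Ppp1r1b 0.45). Thalamus markers rose in 3 of 8 (4 higher and 1 lower; Lef1 0.49, Prkcd 0.41, Plekhg1 0.39). The 2 lists had adjusted p = 0.207 and 0.396 with an estimated correlation. Macrophage markers (1 of 8 rose; 4 adjusted over the list alone, S100a9, a neutrophil alarmin, 2.38) and mural cells (1 of 9; 1; Abcc9 0.29) had adjusted p = 0.512 and 0.396 with an estimated correlation. Leaving out 1 library ended the calls of these lists, with the adjusted p: NRF2 targets (PF+CS 3 0.0614), astrocytes (Veh 3 0.143, PF+CS 1 0.0558), clock genes (Veh 1 0.0944, PF+CS 4 0.167) and macrophages (Veh 1 0.0649, Veh 3 0.213, PF+CS 2 0.0982, PF+CS 3 0.2). Others were mural cells (Veh 3 0.345, PF+CS 2 0.0569, PF+CS 3 0.2), striatum (Veh 1 0.0948, PF+CS 1 0.0555, PF+CS 3 0.0532) and thalamus (Veh 3 0.0567, Veh 4 0.0587, PF+CS 2 0.201).

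In all, 1524 genes were called (864 higher and 660 lower, with 265 changed at least 1.5-fold), 1100 of them without overlap. Among all tested genes, called or not, 13.7% had none, against 2.86% by chance. Hdac6 (0.05), Lepr (0.41), Socs3 (0.96), Ptpn1 (0.19) and Cartpt (−0.30) did not pass by edgeR on all libraries. Lepr passed with the 2 groups alone (0.41, adjusted p = 0.0313), with the meningeal covariate (0.37, 0.0149) and without the 5 libraries low in meningeal markers (0.44, 0.00348), and Socs3 in the last of these too (1.18, 0.0366). Cartpt passed in these 3 fits (−0.30, −0.29 and −0.35, adjusted p 0.00247 to 0.0332), by DESeq2 (−0.29, 0.028) and by voom (−0.31, 0.0301). The count was 710 without Veh 2, 895 without PF+CS 1, 830 without PF+CS 2 and 854 without PF+CS 3. The test of FPKM called 1036 genes (186 higher, 850 lower). Of the 24 genes named by size 18 kept their call in every such fit, all but Snord22, Fzd10, Nkx6-2, Nes, Lrrc10b and Runx1. Of the other genes named here as called, calls were lost in 7 of the 8 fits for Abcc9, Plekhg1 and Trh, in 6 for Agrp, Npy, Gpr6, Mobp and Ppp1r1b, in 5 for Foxo1, Prkcd and S100a9, in 4 for Hsp90aa1 and Hsph1 and in 2 for Gal, Bcl6 and Ptpn2, and the rest kept theirs in all 8. In the authors' deposited table for the same columns, Il1r1 (log2 0.995), Pomc (−0.599), Vgf (−0.472), Lepr (0.295, adjusted p = 0.0274) and Cartpt (−0.251, 0.0156) passed, and Agrp (0.25, 0.124) and Npy (0.244, 0.106) did not. Changes there were at most 1.13 in size (Lcn2 0.147, against 5.35 by edgeR), so only the calls can be compared.

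The libraries of PF+CS were compared with those labelled CS to ask what the ration does in celastrol-treated mice. Cd14 rose by 2.38 (adjusted p = 3.9e-05, edgeR; 4.35 ± 1.38 CPM in PF+CS and 0.848 ± 0.177 CPM in CS, n = 4), Osmr, the oncostatin M receptor, by 1.46 (adjusted p = 0.000711), and Lrg1 by 2.64 (adjusted p = 0.00653). Il1r1 rose by 1.37 (SE 0.23, adjusted p = 0.00937), and Dbp fell by 1.0 (adjusted p = 0.00115). Among feeding genes, Ghsr rose by 0.69 (adjusted p = 0.0245) and Npy1r, a receptor of neuropeptide Y, by 0.35 (adjusted p = 0.0401). Ptpn1 rose by 0.30 (adjusted p = 0.0326). Each of these 3 passed in only 1 fit without a library, that without PF+CS 4 (adjusted p in the other 7: 0.054 to 0.0989, 0.0702 to 0.177 and 0.0612 to 0.145). In that fit Socs3 passed too (1.34, adjusted p = 0.0291).

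Other genes that rose were Lcn2 (4.94, adjusted p = 0.0584 without CS 1 and 0.0582 without CS 4), Tmem252 (3.89), Cdkn1a (2.98), Cebpd (2.07), Ptgs2 (1.95), Angptl4 (1.83), Pla2g3 (1.73), Map3k6 (1.66) and Pmaip1 (1.46). Lower were Sgk2 (−1.53), a kinase related to Sgk1, Serpinb1a (−1.24) and Insc (−1.0), of spindle orientation. Edn3 (−0.87), an endothelin, Trim59 (−0.78), a ubiquitin ligase, Slc17a8 (−0.76), a vesicular glutamate transporter, Hpgd (−0.70), which degrades prostaglandins, and Sfrp5 (−0.69), a Wnt inhibitor, were lower too. Tmem88b (−0.68), Padi2 (−0.68) and Gjb1 (−0.66), genes of mature oligodendrocytes, were lower as well.

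Glucocorticoid-responsive genes rose in 8 of 20 with 0 lower (17 adjusted over the list alone, adjusted p = 7.71e-21, camera, adjusted p = 0.106 with an estimated correlation; Plekhf1 0.79, Arrdc2 1.29, Pdk4 1.37). Cytokine STAT3 genes rose in 6 of 19 (13 adjusted over the list alone, Ch25h 2.40, adjusted p = 0.0915 with an estimated correlation) and NF-kB genes in 5 of 14 (7; Nfkbia 0.86, adjusted p = 0.0915 with an estimated correlation). Heat shock genes rose in 4 of 20 (16 adjusted over the list alone, Hsp90aa1 0.25, Hsph1 0.45, Hsp90ab1 0.15, Ahsa1 0.25). The unfolded protein response rose in 1 of 23 (5 adjusted over the list alone, Hsp90b1 0.18) and fatty acid oxidation in 3 of 16 (4, with Pdk4 and Angptl4). The 3 lists had adjusted p = 0.151 with an estimated correlation. Genes of the leptin signalling list rose in 2 of 20 (4 adjusted over the list alone, Il1r1, and Ptpn1, which dampens the pathway). Insulin and FoxO targets rose in 2 of 12 (6 higher and 1 lower; Sesn1 0.36, Bcl6 0.69). These had adjusted p = 0.14 and 0.185 with an estimated correlation. Oligodendrocyte genes fell in 2 of 10 (8 adjusted over the list alone, Ermn −0.39, Mbp −0.22, adjusted p = 0.106 with an estimated correlation). The list stood at a mean log2 CPM of 7.22 ± 0.0753 in CS (SD, n = 4) and at 6.65 to 6.70 in 3 PF+CS libraries, with PF+CS 4 at 7.14. Clock genes fell in 5 of 17 and rose in 2 (10 and 4 adjusted over the list alone, Bhlhe41 −0.34, Bhlhe40 −0.33, Npas2 0.44, adjusted p = 0.103 with an estimated correlation). Cholesterol synthesis fell in 2 of 19 (6 adjusted over the list alone, Insig1 −0.29, Hsd17b7 −0.36, adjusted p = 0.151 with an estimated correlation). The interferon response (0 of 15 fell, 0 adjusted over the list alone) and neurons (0 of 10, 0) were called lower, with adjusted p = 0.457 and 0.414 with an estimated correlation. Lists that lost their call without 1 library, with the adjusted p, were fatty acid oxidation (PF+CS 3 0.0774), the interferon response (PF+CS 2 0.0605) and neurons (PF+CS 1 0.0548, PF+CS 3 0.0502).

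In all, 392 genes were called (264 higher and 128 lower, with 128 changed at least 1.5-fold), 333 of them without overlap. Among all tested genes, called or not, 10.1% had none, against 2.86% by chance. Hdac6 (0.03), Lepr (0.27), Socs3 (1.11), Agrp (0.45), Npy (0.07), Pomc (−0.10) and Cartpt (0.01) did not pass by edgeR. Socs3 passed by voom (1.1, adjusted p = 0.0369), without the 5 libraries low in meningeal markers (1.38, 0.0318) and in the authors' deposited table from the CS and PF+CS columns (0.277, 0.0073). The count was 113 without CS 1, 222 without CS 2, 212 without CS 3, 126 without CS 4, 120 without PF+CS 1, 116 without PF+CS 2, 157 without PF+CS 3 and 961 without PF+CS 4. Cd14, Cebpd, Dbp, Lrg1, Osmr, Padi2, Pla2g3, Pmaip1, Serpinb1a, Tmem252 and Trim59 were the 11 of 24 named by size that kept their call in every such fit. Il1r1, Ch25h, Arrdc2, Hsp90aa1, Hsph1, Insig1, Sesn1, Bhlhe40 and Bhlhe41 did so too. By voom 971 genes were called, with the 2 groups alone 598 and in the test of FPKM 50.

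The interaction asks whether celastrol acts differently under the ration than with free food. No gene was called: Pomc had log2 0.65 (SE 0.19, adjusted p = 0.913), Ptpn1 0.23, Lepr 0.23, Socs3 0.21, Agrp −0.20, Cartpt 0.16, Npy −0.12, Il1r1 −0.11 and Hdac6 0.10. By edgeR 0 genes passed with 741 at an unadjusted p under 0.05, by DESeq2 0 with 511 and by voom 0 with 856. Of the lists, fatty acid oxidation (higher) and neurons (lower) were called by camera (adjusted p = 0.0266 for each, adjusted p = 0.584 and 0.819 with an estimated correlation), as were oligodendrocytes (lower) and ribosomal proteins (higher), at adjusted p = 0.0268 (adjusted p = 0.819 with an estimated correlation). No member of these passed over all genes. Every one of these list calls ended without some libraries, with the adjusted p: fatty acid oxidation (Veh 1 0.0722, Veh 4 0.0696, PF 2 0.0672, CS 2 0.0594, PF+CS 3 0.199), neurons (Veh 1 0.13, Veh 4 0.0557, PF 2 0.158, PF+CS 1 0.0579, PF+CS 3 0.141), oligodendrocytes (Veh 1 0.138, Veh 4 0.0696, PF 1 0.0513, PF 2 0.0672, PF 3 0.162, CS 1 0.0995, PF+CS 1 0.0932, PF+CS 2 0.0646, PF+CS 3 0.238) and ribosomal proteins (Veh 1 0.13, Veh 2 0.12, Veh 4 0.0557, PF 2 0.052, PF 3 0.162, PF 4 0.232, CS 4 0.218, PF+CS 1 0.0579, PF+CS 3 0.238).

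Changes were related across genes, which are not independent replicates. By the column names, CS minus Veh and PF+CS minus PF are celastrol effects, with free food and under the ration. They correlated at r = 0.281 (0.164 without CS 4), and at 0.055 with DESeq2, whose fit also held the low-count genes left out by the filter. Heg1 and Col11a1 were among 6 genes higher in both (0.0396 expected by chance), and Vgf was the 1 lower in both (0.00589 expected). Vgf was also called lower in PF minus Veh, a call kept in 3 of 8 fits without 1 library. Genes called higher had a median transcript length of 7077 bases in CS minus Veh and 7058.5 in PF+CS minus PF, against 3446.5 for all tested. Whether a trend with length gave part of the shared calls was not tested. PF minus Veh and PF+CS minus CS are by the same names effects of the ration, without and with celastrol. This pair correlated at r = 0.642 (0.227 with DESeq2, again with the low-count genes). Genes higher in both numbered 119 (6.22 expected), Lcn2, Cebpd and Il1r1 among them. There were 45 lower in both (1.64 expected), Dbp and Insig1 among them. If the names of the deposited tables are right instead, the first pair is that of the ration and the second that of celastrol. CS minus Veh and PF minus Veh share the Veh libraries, and their r of 0.331 (0.34 on log2 CPM) compares with 0.481 (0.446 to 0.504 over 20 runs) in data simulated without any effect. The covariance went the other way, at 0.01301 against a simulated 0.01207 (0.01099 to 0.01298). With the Veh libraries split between the 2 contrasts, r was −0.09 to 0.196 (median 0.038). These values do not settle whether the 2 contrasts share changes. Of 36 lists, camera called 9 in CS minus Veh, 16 in PF minus Veh, 20 in CS minus PF, 14 in PF+CS minus PF, 18 in PF+CS minus Veh and 13 in PF+CS minus CS. By fry the counts were 5, 11, 14, 3, 16 and 12.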

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

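The tests of the regroupings, of the table names, of meningeal tissue and of the GC and length trend were chosen after the results were seen, and the test of exchanged libraries and that of the ribosomal and oxidative phosphorylation lists before. For meningeal tissue, the correlation of its markers with the glucocorticoid list over the 8 PF and PF+CS libraries was tested first, met neither bound set for it, and was replaced because the libraries fall into 2 clusters.

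A library far from the 3 others of its group was looked for by Dixon's ratio (gap over range) in 176 genes and 8 measures per library, 736 groups of 4, of which 39 passed and 36.8 were expected by chance. The mean log2 CPM of oligodendrocyte markers was 7.14 in PF+CS 4 against 6.65 to 6.70 in the other PF+CS libraries (ratio 0.898). In PF+CS 4 the ratio also passed for Cnp (0.874, 225 CPM against 173 to 179), Tmem88b (0.932, 79.3 against 50.8 to 52.7), Gjb1 (0.862, 7.45 against 5.05 to 5.38), Ghsr (0.896, 9.13 against at most 16.8), Pomc (0.876, 20.2 against 16.3 to 16.8), Gbp4 (0.864, 2.70 against 0.631 to 0.913) and Sirt3 (0.893, 15.8 against 19.1 to 19.5). Those in CS 1 were Arc (0.953, 11.8 against 7.55 to 7.75), C1qb (0.864, 23.2 against 19.2 to 19.8), Ermn (0.855), Kmt2d (0.846), Lrrc10b (0.834) and Map3k6 (0.835). Those in Veh 3 were Sgk1 (0.948, 110 against 35.4 to 39.3), Ddit4 (0.878), Arhgef2 (0.861), Clec14a (0.845), Ly6c1 (0.863) and Sele (ratio 1, its only count in Veh). In PF 1 they were Cartpt (0.927, 68.6 against 53.3 to 54.4), Pomc (0.885, 23.6 against 16.7 to 17.5), Haus5 (0.878), P2ry13 (0.875) and Rplp1 (0.876). The rest were Cited1 (0.855), Selp (ratio 1, its only count in Veh) and Slc6a11 (0.942) in Veh 2, Cnr1 (0.902) and Sox18 (0.858) in Veh 4, Coro6 (0.886) and Slc17a8 (0.895) in Veh 1, Enpp6 (0.915) and Plekhg1 (0.866) in PF 4, Cnot3 (0.858) in PF 2, Fzd10 (0.871) in CS 2, Nes (0.867) in CS 4, P2ry13 (0.938) in PF+CS 3 and Tdrd9 (0.993) in PF+CS 1.

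Between the rationed and freely fed groups the celastrol effect was called different by camera at the preset correlation in 4 lists: fatty acid oxidation (adjusted p = 0.0266, median log2 0.14), neurons (0.0266, −0.07), oligodendrocytes (0.0268, −0.15) and ribosomal proteins (0.0268, 0.05). None of the 4 was called by camera with an estimated correlation (adjusted p = 0.584, 0.819, 0.819 and 0.819 with an estimated correlation) or by fry. In 78 of 100 groupings, the real one included, at least as many lists were called. Those groupings shuffled all 16 libraries and so carry the differences between the groups. They therefore cannot show how many list calls an absent interaction would give. Genes with FPKM values but 0 counts were tested by themselves with limma on log2 FPKM with 1 added, so their adjusted p is over 57 genes only. Among them Hist1h4m, a histone gene, fell by 0.48 in CS minus Veh (adjusted p = 0.0368). Gm15319 fell by 0.24 in PF minus Veh (adjusted p = 0.0259) and reached −0.25 in PF+CS minus Veh (adjusted p = 0.0156). Hbb-bs, a haemoglobin chain, had an FPKM of 5.15 in CS 1, at most 0.00312 in any Veh library and at most 0.00432 in any other library. Other haemoglobin genes had no higher group mean in CS than in Veh. Mean FPKM was 82 against 107 for Hbb-b1, 24.3 against 35.3 for Hbb-bt and 33.1 against 45.1 for Hba-a1.

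As many genes as in the real groups were called in 1 of 35 splits of the libraries, the real one, in CS minus Veh (132, next 2), PF minus Veh (537, next 335), CS minus PF (561, next 36), PF+CS minus Veh (1524, next 155) and PF+CS minus CS (392, next 16). In PF+CS minus PF this held for 3 of 35 splits, the highest with 320 genes against 14. In the interaction it held for 100 of 100 (highest 24), by construction, because the real groups called 0 genes. For gene lists the splits with as many calls were 8 of 35 in CS minus Veh, 1 of 35 in PF minus Veh, 1 of 35 in CS minus PF, 7 of 35 in PF+CS minus PF, 4 of 35 in PF+CS minus Veh and 8 of 35 in PF+CS minus CS, and 78 of 100 in the interaction. The counts of lists in 5 of the 7 contrasts, and of genes in PF+CS minus PF, were thus matched by more splits than the real one. A regrouped split can still hold most of a group on one side and so carry part of a real difference. The splits therefore cannot show what data without any difference would give.

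The names of the deposited comparison tables were weighed first. Exchanging PF and CS made all 5 names match their columns, against 2 of 5 without it, which fits an exchange on one side. Which side is wrong could not be told. The sample titles carry the same names as the count columns. The only check made was the match of libraries across the count and FPKM tables, which gave 0 sources that decide. All 16 libraries matched their own name across the count and FPKM tables. Both carry the same column names, so that match could not decide the question.

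The uneven strength of the response among the PF and PF+CS libraries was weighed next. With PF 1, PF 2, PF 3 and PF+CS 4 on one side, 320 genes were called. An exchange of PF 4 and PF+CS 4 could give this. The signed mean change of PF 4 over the genes called in CS minus Veh was −0.007, against −0.11, −0.031 and −0.008 in the other PF libraries. That of PF+CS 4 was 0.071, against 0.053, 0.125 and 0.081 in the other PF+CS libraries. By the bounds set beforehand the test could not tell, because PF 4 lay just above PF 3. Yet PF 4 lay below every PF+CS library and PF+CS 4 above every PF library. Other measures went the other way. The glucocorticoid list was at 5.76 in PF 4, among the other PF+CS libraries (5.51 to 5.90), though PF 1 at 5.57 was too. In PF+CS 4 it was at 4.85, below every PF library. Oligodendrocyte markers were at 6.66 in PF 4 and 7.14 in PF+CS 4, against 6.65 to 6.70 in the other PF+CS libraries. An exchange was thus left open. Meningeal tissue alone did not account for the 320 calls, since 258 genes were still called with a term for its markers. How much each rationed mouse ate or how stressed it was is not stated in the sources used here.

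Short transcripts among the genes lower in CS minus Veh were weighed last. With an offset for GC content and length, 79 of 123 called genes (64.2%) stayed called, all 123 kept their sign and the median absolute log2 change of those that left went from 0.24 to 0.186, while the rank correlation of change with length went from 0.204 to 0.005. The median change of the ribosomal protein list went from −0.127 to −0.054 and that of the oxidative phosphorylation list from −0.099 to −0.062. A library-wide trend and lower sets of short genes could each give these values, and the tests could not tell them apart.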

How the results depend on the processing

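The tests with a meningeal covariate, without 5 libraries and with the GC and length offset were added after results were seen. In simulated data 73 of 100 effects of 1.5-fold were recovered in PF minus Veh and 122 of 200 in the interaction, so effects of that size can be missed at the depth used. Where the cause of a moved value is not given below, the cause was not tested. Named gene results kept direction and call in 354 of 381 with DESeq2, 389 of 397 with RLE scaling, 372 of 397 with voom, 382 of 389 with the filter at mean CPM 1, 370 of 397 without a filter, 312 of 377 with the 2 groups alone, 365 of 395 with the offset, 377 of 397 with the covariate, 319 of 397 without the 5 libraries, 190 of 397 with FPKM and 2320 of 3248 with 1 library left out. Gene list calls kept theirs in 1 of 94 with an estimated correlation, 57 of 94 with fry and 667 of 784 with 1 library left out.

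With 1 library left out, the genes called ranged from 10 (without CS 4) to 242 (without Veh 3) in CS minus Veh, 111 to 810 in PF minus Veh, 190 to 841 in CS minus PF, 1 to 24 in PF+CS minus PF, 710 to 2007 in PF+CS minus Veh, 113 to 961 in PF+CS minus CS and 0 to 0 in the interaction. Lists called ranged from 6 to 12, 13 to 17, 15 to 20, 9 to 18, 15 to 20, 11 to 19 and 0 to 6. The correlation of the celastrol effects ranged from 0.164 to 0.34 and that of the ration effects from 0.545 to 0.673, both named by the column names. That of CS minus Veh with PF minus Veh ranged from 0.241 to 0.477. Fewer libraries leave less power by construction, and a count that grew without 1 library was not explained.

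In CS minus Veh, DESeq2 called 282 genes (141 higher, 141 lower), the 2 groups alone 257 (91, 166), voom 228 (77, 151), FPKM 11 (0, 11), the covariate 207 (82, 125), the fit without the 5 libraries 342 (138, 204), an adjusted p of 0.01 18 (6, 12) and a 1.5-fold threshold 6 (0, 6). The share of higher genes moved with RLE scaling (110; 49 higher, 61 lower), the filter at mean CPM 1 (111; 51, 60) and the offset (115; 54, 61). PF minus Veh gave 284 with the 2 groups alone, 87 with FPKM (35 higher, 52 lower), 114 at 0.01 and 122 at 1.5-fold. CS minus PF gave 119 with FPKM, 139 at 0.01 and 137 at 1.5-fold. PF+CS minus PF gave 29 with DESeq2, 7 with the 2 groups alone, 5 with voom, 0 with FPKM, 0 without the 5 libraries, 1 at 0.01 and 0 at 1.5-fold. PF+CS minus Veh gave 529 at 0.01, 265 at 1.5-fold and 1036 with FPKM (186 higher, 850 lower). PF+CS minus CS gave 598 with the 2 groups alone, 971 with voom, 50 with FPKM, 1013 without the 5 libraries, 90 at 0.01 and 128 at 1.5-fold. Stricter thresholds give fewer genes by construction. The offset was also applied to 2 lists in PF+CS minus Veh, where the median change of ribosomal proteins went from −0.12 to −0.057 and that of oxidative phosphorylation from −0.125 to −0.063.

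Lists called with an estimated correlation numbered 0 in CS minus Veh, 0 in PF minus Veh, 0 in CS minus PF, 1 in PF+CS minus PF, 0 in PF+CS minus Veh, 0 in PF+CS minus CS and 0 in the interaction. By fry they numbered 5 in CS minus Veh, 3 in PF+CS minus PF and 0 in the interaction. PF+CS minus PF gave 7 lists without the 5 libraries, and the interaction 2 with FPKM and 1 with the covariate. By the column names, the correlation of the celastrol effects was 0.055 with DESeq2 and 0.044 without a filter. That of the ration effects was 0.227 with DESeq2, 0.162 without a filter and 0.506 with FPKM. The DESeq2 fit also held every gene with a count, so its values, like those without a filter, include low-count genes that the main values leave out.

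The replicate numbers do not pair the libraries: over 24 pairs with the same number the correlation of deviations was −0.42 to 0.33, 5 were above 0.1, and 1 of 16 libraries correlated best with its own number. With the replicate block, 99, 401, 375, 13, 1221, 223 and 0 genes were called in the 7 contrasts, and with the block and the offset 345 in PF minus Veh and 6 in PF+CS minus PF.

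The direction of some results turned, none of which was called under the setting. The meningeal list turned with the covariate in CS minus PF (adjusted p = 0.624) and PF+CS minus PF (0.889), since the covariate takes out its signal, and the interferon response list turned in PF+CS minus PF without the 5 libraries (0.448) and without PF+CS 4 (0.986, against 0.00461 without PF+CS 2). In CS minus Veh, Prrt1 was at −0.01 and Scarna2 at 0.00 with FPKM. Hdac6 turned in CS minus Veh (−0.07 with FPKM, −0.03 without Veh 4), PF+CS minus Veh (−0.06 with FPKM) and PF+CS minus CS (−0.01 without the 5 libraries, 0.00 without PF+CS 4, up to 0.07 without PF+CS 3). Lepr turned in PF minus Veh (−0.03 with FPKM, −0.01 with the offset, −0.02 with block and offset, 0.00 without Veh 2, −0.02 without Veh 3, −0.19 without PF 4, up to 0.19 without PF 2), CS minus PF (−0.09 with the covariate, −0.08 without the 5 libraries, −0.05 without PF 2) and the interaction (−0.05 without the 5 libraries). Socs3 turned in PF+CS minus PF (−0.01 with FPKM, −0.06 with the covariate, −0.15, −0.09, −0.03 and −0.16 without PF 2, PF 3, PF+CS 1 and PF+CS 2) and the interaction (0.00 without PF 2, −0.01 without PF+CS 2, up to 0.48 without PF 4). Agrp turned in PF+CS minus PF (−0.04 with the covariate, 0.00 without the 5 libraries, −0.05, −0.04, −0.02 and −0.05 without PF 2, PF 3, PF+CS 1 and PF+CS 3, up to 0.17 without PF 4). Npy turned in CS minus PF (0.00) and the interaction (0.01) without the 5 libraries and in PF+CS minus CS without CS 4 (−0.03) and PF+CS 3 (−0.04, up to 0.16 without CS 2). Pomc turned in CS minus PF (−0.03, 0.00, 0.00 and −0.04 without PF 2, PF 3, PF 4 and CS 1, up to 0.14 without PF 1) and PF+CS minus PF (0.03 without PF 1). Cartpt turned in PF+CS minus CS (−0.02, −0.04, 0.00, −0.01 and −0.04 without CS 3, CS 4, PF+CS 1, PF+CS 3 and PF+CS 4, up to 0.09 without CS 2). Ptpn1 turned in PF minus Veh (−0.02 without PF 4, up to 0.13 without PF 3) and Il1r1 in the interaction (0.06 without CS 4, down to −0.30 without Veh 3).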

Other observations

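The tests of repeated libraries and of genes with FPKM values only were chosen after the data were examined. Several genes named by the rule for list members are not described above. Gad1, the enzyme that makes GABA, fell by 0.24 in PF+CS minus Veh (SE 0.04, BH adjusted p = 0.000553, edgeR; 272 ± 9.78 CPM in PF+CS and 322 ± 8.15 CPM in Veh, n = 4), and Arc, an immediate early gene of active synapses, fell by 0.59 (SE 0.14, adjusted p = 0.00832; 6.17 ± 0.574 CPM and 9.30 ± 0.847 CPM, n = 4). Both passed in every fit without 1 library (Gad1 −0.26 to −0.22, Arc −0.65 to −0.53).

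C1qb, a complement subunit made by microglia, fell by 0.37 in CS minus PF (SE 0.08, adjusted p = 0.0105) and rose by 0.40 in PF+CS minus CS (adjusted p = 0.0074). The first call ended without CS 4 (adjusted p = 0.0539), and both ended in the test of FPKM (adjusted p = 0.0812 and 0.0867). Among deacetylases, Hdac7, a class II enzyme of vessels, rose by 0.30 in CS minus PF (adjusted p = 0.0149; 0.110 in the test of FPKM), and Sirt3, the mitochondrial sirtuin, fell by 0.33 in PF+CS minus Veh (adjusted p = 0.0138; 0.0528 without Veh 2). The list of deacetylases and sirtuins was called in no contrast.

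Of the genes looked up, 59 of 173 had an exon that overlaps another gene, 17 of them on the same strand, among them Agrp with Gm5914. The second table held 57 genes with a mean FPKM of at least 1 and 0 counts in the count table. Over 120 pairs of libraries the lowest chi-square per degree of freedom between the counts of a pair was 1.64, so no pair was a repeat of the same counts.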
